A study of Homo sapiens with 24 samples.

How the data were processed

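RNA from 2 human prostate cancer cell lines was measured on 24 arrays. Each line gave 6 groups of 2 arrays, which the labels call biological replicates. The groups were stable pools carrying 1 of 4 MYCL open reading frame constructs (named here, as in the labels, BC011864, NM_001033081, NM_001033082 and NM_005376), a pool carrying the empty vector, and untransfected cells. Per the labels, medium contained 250 µg/ml geneticin, and the same text is given for the untransfected cells. Total RNA was extracted with a silica column kit and labelled as biotinylated single-stranded cDNA for an Affymetrix whole-transcript array, per the labels' protocols. The labels describe 1 pool per construct and line and do not say whether its 2 arrays came from separate transfections. P-values therefore measure the spread between these arrays, which may be smaller than the spread between independent pools.

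The deposited values are log2 expression values that the authors made with RMA, using R 3.0.3 and affy 1.40.0 per the submitters' processing notes. RMA corrects background, normalizes between arrays by quantiles and summarises probes by median polish. The array version, the probe set definition file and the genome build were not given in the sources used here, and no coordinates are printed. The table had 26194 rows with identifiers built on Entrez gene numbers, no missing value and no column left unassigned to a sample. Of these rows, 24630 carried 1 gene symbol in the probe table used here, 1564 were unnamed in it and 0 named several genes. Each named gene had 1 row. The 24630 named genes were tested. Column medians lay between 6.59 and 6.76 in 22RV1 and between 5.89 and 6.23 in LNCaP, so the lines appear to have been normalized separately. Levels set across the lines are therefore given with quantile-normalized values beside them. Detection calls were not used here, and the number of arrays limits the precision.

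Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 24 arrays, with 1 mean per group, contrasts between groups and empirical Bayes moderation without a trend. P-values were adjusted by the Benjamini-Hochberg method over the 24630 genes within each comparison, and genes with adjusted p under 0.05 were called. Every adjusted p in the text comes from limma unless another source is named. Comparisons were each construct against vector within its line, the mean of the 4 constructs against vector in each line and over both lines, the difference of that effect between the lines, vector against untransfected cells, and the untransfected lines against each other. A moderated F test compared the 4 constructs within each line. MYCL was tested in each construct pool, with p adjusted over its 8 comparisons and over all genes.

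Gene lists were fixed before the data were examined, 29 in all, and 27 had at least 3 measured genes. The other 2, histones under older symbol prefixes and mitochondrially encoded genes, matched 0 named rows. Lists were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01, adjusted over the lists tested in each comparison, and again with a correlation estimated from the arrays. Beside the members called over all genes, the number called with p adjusted over the list alone is given where it differs. MYCL was named throughout. The other named genes were those with the highest and lowest log2 differences among called genes, up to 10 at each end for comparisons of means and of controls and up to 5 for single constructs, and in comparisons within a line only genes with all treated arrays on 1 side of both control arrays were taken. Olfactory receptors, small nucleolar, spliceosomal and microRNAs, symbols of unplaced or uncharacterised genes and Y-linked genes were passed over. Up to 4 members with the smallest p were taken from each list. Genes named outside this rule are marked as chosen after their values were seen.

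The fitting and calling steps were tested on simulated data with 24630 genes. Noise was independent and normal, with 1 SD per gene taken from these arrays and equal in all groups. In the arrays themselves the SD of replicate differences was unequal, 0.268 for LNCaP BC011864 and 0.135 for LNCaP vector. The shares below therefore describe the method under its own assumptions. For BC011864 against vector in LNCaP, simulated log2 differences of 0.5, 0.75, 1 and 1.5 were called in 52%, 76.8%, 94% and 98.4% of changed genes, and 5.86% of calls were false. For the mean of 4 constructs in LNCaP the shares were 67.6%, 91.2%, 96.8% and 100%, with 5.83% false calls.

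Alternatives fixed before the data were examined were a replicate block, each line fitted alone, the 30% of genes with the lowest means left out, variance moderation with a trend and robust settings, quantile normalization of all arrays together, unnamed rows included, untransfected cells as the control, each array left out in turn, and the estimated correlation for lists. Averaging the rows of a gene was also planned and had nothing to average. Chosen after seeing the data were the interquartile range of each array as a covariate, array weights, and leaving out the second arrays of the LNCaP BC011864 and NM_005376 pools, whose replicate pairs differed most among the LNCaP construct pools. Because comparisons share the vector arrays, overlaps and correlations between constructs were set beside 100 simulations of unchanged groups against shared controls. These too drew independent noise with an equal spread in all groups. Correlations with 1 vector array per construct were added after seeing the data. Levels of Y-linked genes are not reported.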

Results

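Gene expression was measured in 22RV1 and LNCaP, 2 human prostate cancer cell lines that express the androgen receptor. The design varied MYCL, which encodes L-Myc, a transcription factor of the MYC family. Each line was represented by 4 stable pools with different MYCL open reading frames, 1 empty-vector pool and untransfected cells, with 2 arrays per group and 24 arrays in all. The interquartile range of single arrays lay between 2.83 and 3.08 log2 units in 22RV1 and between 2.84 and 3.28 in LNCaP. Across genes, the SD of the difference between the 2 arrays of a group was 0.131 to 0.196 in 22RV1. In LNCaP it reached 0.357 for NM_005376, 0.268 for BC011864 and 0.25 for untransfected cells, against 0.135 for vector.

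MYCL was measured first, as the transfected gene. In LNCaP its log2 value averaged 7.56 ± 0.066 (SD, n = 2) in vector cells, 8.01 ± 0.022 in the NM_001033082 pool and 7.91 ± 0.2 in the NM_005376 pool. These 2 pools exceeded vector by 0.45 ± 0.097 (SE) and 0.35 ± 0.097, or 1.37-fold and 1.27-fold, with adjusted p = 0.00198 and 0.0101 over the 8 MYCL comparisons. In 22RV1 the same constructs exceeded vector (8.04 ± 0.016) by 0.26 and 0.31, or 1.2-fold and 1.24-fold, with adjusted p = 0.0305 and 0.0138. MYCL did not pass the test in the BC011864 and NM_001033081 pools, where differences were 0.11 and 0.019 in 22RV1 and 0.082 and -0.036 in LNCaP. Both arrays of each pool that passed lay above both vector arrays. Adjusted over all genes, only NM_001033082 in LNCaP passed (adjusted p = 0.0481), and that call was lost with each line fitted alone (adjusted p = 0.422), with quantile normalization (0.103), against untransfected cells (0.119) and without any 1 of 18 of the 24 arrays. Its adjusted p ranged from 0.000245 to 0.546 over all alternatives. Where the probes lie relative to the transfected reading frames was not given in the sources used here, so the probe set may miss part of the transfected message.

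**Figure D1:**
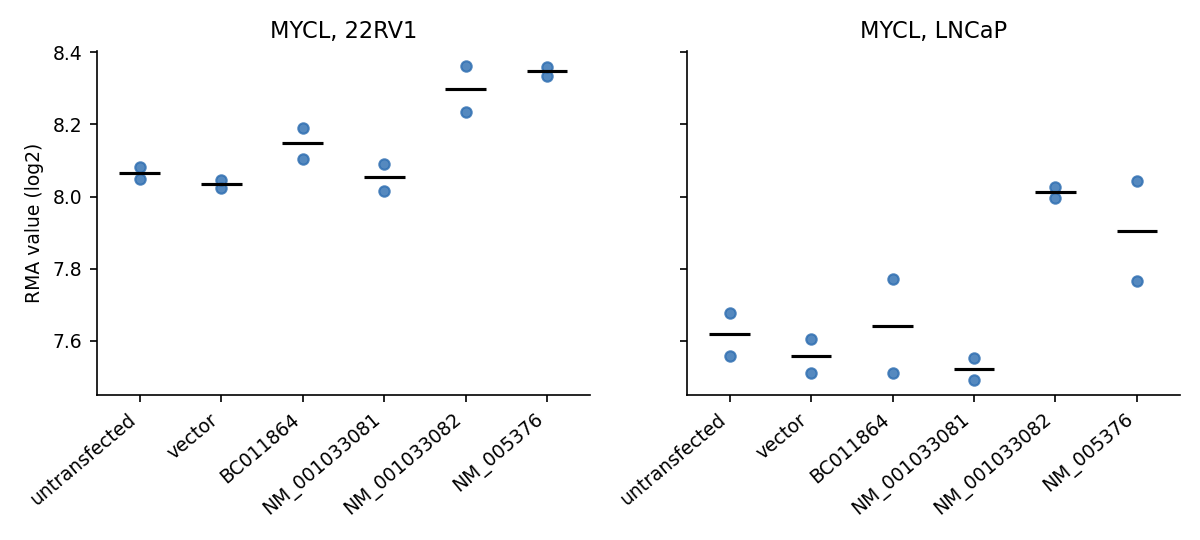
MYCL values (RMA, log2) of each array by group, with 22RV1 on the left and LNCaP on the right; points are single arrays and black lines are the means of 2 arrays. The NM_001033082 and NM_005376 pools lie above vector in both lines, with means of 8.30 and 8.35 in 22RV1 and 8.01 and 7.91 in LNCaP.

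Averaged over the 4 construct pools of LNCaP, RIPOR2, an inhibitor of RhoA signalling, fell by 1.06 ± 0.068 (SE) on the log2 scale against vector (adjusted p = 4.21e-07), and SLITRK3, a synaptic adhesion protein, fell by 0.92 ± 0.12 (adjusted p = 0.00236). SYT4, a vesicle synaptotagmin, fell by 0.76, CADPS2, which acts in dense-core vesicle release, by 0.68, and DSC3, a desmosomal cadherin, by 0.62. NRP1, a semaphorin and VEGF coreceptor, fell by 0.56 and the bombesin receptor gene GRPR by 0.52, and GLCCI1-DT, QNG1 and PLAAT3 also fell. All 8 construct arrays lay below both vector arrays for each of these 10 genes. OR51E1, an olfactory receptor gene chosen after its values were seen, had the largest fall among the 28 genes called, 1.41 ± 0.091. Against untransfected cells OR51E1 differed by -0.253 and was not called (adjusted p = 0.295), as vector stood 1.16 above them. Against vector, 6 genes rose and 22 fell in all.

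KLK3, which encodes prostate-specific antigen and is induced by the androgen receptor, averaged 0.71 ± 0.077 log2 units lower over the 4 LNCaP constructs (log2 difference -0.71, adjusted p = 0.000311). It fell in the BC011864 and NM_001033082 pools and differed by -0.063 in the NM_001033081 pool and -0.33 in the NM_005376 pool (adjusted p = 0.14), neither called. Against untransfected cells the mean difference was -0.29 (adjusted p = 0.182). It lay below both vector arrays on 7 of the 8 construct arrays. Of 26 measured androgen-induced genes, KLK3 alone was called (1 higher and 4 lower adjusted over the list alone) and the list median was -0.11 (camera adjusted p = 3.95e-07, and 0.38 with an estimated correlation). Luminal epithelium markers had 1 of 15 called, again KLK3 (2 lower adjusted over the list alone), with a median of -0.091 (adjusted p = 0.000144, and 0.398 with an estimated correlation). Amino acid and ATF4 response genes had 0 of 26 called (3 lower adjusted over the list alone) and a median of -0.097 (adjusted p = 6.93e-09, and 0.38 with an estimated correlation). Glycolysis and hypoxia genes had 0 of 28 called (1 lower adjusted over the list alone) and a median of -0.11 (adjusted p = 3.12e-09, and 0.38 estimated). Small nucleolar RNAs had 2 of 323 called higher, SNORA26 (1.20) and SNORA64 (1.00), 26 adjusted over the list alone, and a median of 0.13 (adjusted p = 7.79e-11, and 0.451 estimated). Against untransfected cells SNORA26 differed by -0.20 and SNORA64 by 0.031, neither called, and the list median was -0.12 with 0 members called. Oxidative phosphorylation (median 0.19, 0 of 33 called, adjusted p = 0.451 with an estimated correlation), cytosolic ribosomal proteins (median 0.14, 0 of 51 called, 0.486) and p53 target genes (median 0.076, 0 of 22 called, 0.38) likewise passed only with the preset correlation. The MYC network, with MYCL among its 14 measured members, had a median of 0.0089 and 0 called, and MYC-induced ribosome biogenesis genes a median of 0.03 and 0 of 40 called (camera adjusted p = 0.711 and 0.468).

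The LNCaP result depended on its control. Against untransfected cells the mean of the constructs called 34 genes, 7 of which were called in the same direction against vector: CLEC7A, RTN1 and TTR higher, and H3C11, LINC01446, QNG1 and RIPOR2 lower, named here after their values were seen. H3C11 was low in the BC011864 pool (5.46 and 6.05), while the arrays of the other 3 construct pools read 8.43 to 8.49 and vector 8.36 and 8.54. SYT4 and DSC3 differed from untransfected cells by 0.21 and -0.073 and were not called. Without vector replicate 1 or 2 the count of 28 fell to 4 or 7, and without NM_005376 replicate 1 it was 45.

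**Figure D2:**
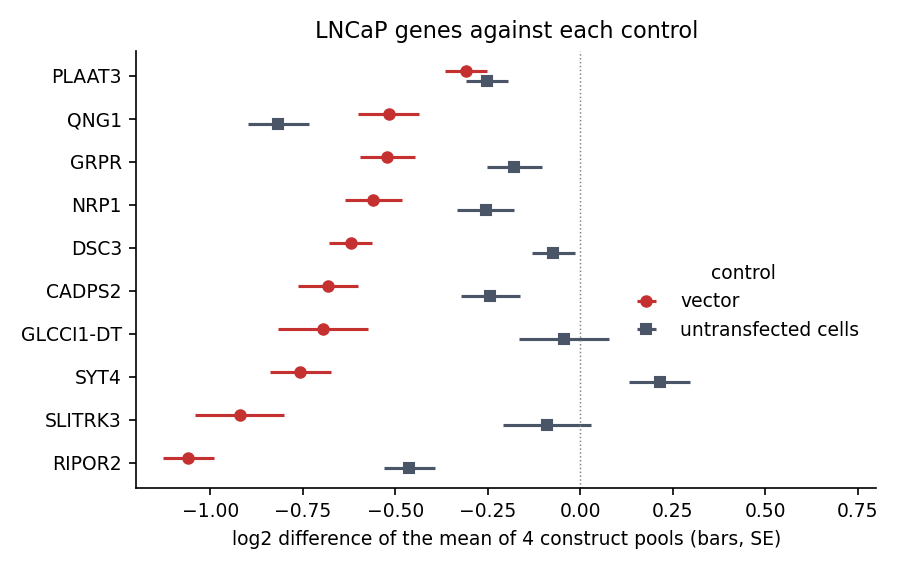
Log2 differences of the mean of the 4 LNCaP construct pools for the 10 genes named by rule, against vector (circles) and against untransfected cells (squares), with bars of 1 SE; the horizontal axis is in log2 units. Differences from vector run from -1.06 for RIPOR2 to -0.31 for PLAAT3, and SYT4 lies at 0.21 against untransfected cells.

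In 22RV1 the mean of the 4 constructs differed from vector in 18 genes, 12 higher and 6 lower. TNFSF10, the gene of the death ligand TRAIL, fell by 0.68 ± 0.087 (adjusted p = 0.0155), and the epithelial sodium channel subunit SCNN1B fell by 0.65. The membrane glycoprotein gene GPNMB, TRBV5-7 and ADM, which encodes the peptide hormone adrenomedullin, fell by 0.54, 0.55 and 0.48. Among genes that rose were the membrane-type metalloproteinase MMP16 (0.67 ± 0.1), the transcription repressor SNAI2 (0.66), the mannosidase MAN1A1 (0.64), the growth factor receptor EGFR (0.63), DHRS2 (0.44) and COLCA1 (0.42). TRHDE, ADGRL2, RGS5 and SMC1B rose by 0.36 to 0.39. For each gene named here all 8 construct arrays lay on 1 side of both vector arrays.

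Gene lists in 22RV1 moved little. DNA replication genes had a median of 0.081 and mitosis genes 0.11, with 0 of 34 and 0 of 35 called (camera adjusted p = 4.67e-07 and 1.33e-07, and 0.707 and 0.766 with an estimated correlation). MYC-induced ribosome biogenesis genes had a median of 0.074 with 38 of 40 above 0 and 0 called (adjusted p = 5.6e-06, and 0.766 estimated). Nucleotide and polyamine synthesis (median 0.045, 0 of 28 called), endoplasmic reticulum chaperones (0.072, 0 of 18), NF-kB and inflammatory genes (-0.08, 0 of 21) and leukocyte and endothelial markers (-0.12, 0 of 12) passed with the preset correlation, each with adjusted p = 0.766 when it was estimated. MYC-repressed genes had 0 of 14 called and a median of -0.072 (adjusted p = 0.585). Fibroblast and mesenchymal markers had 1 of 22 called, SNAI2 (2 higher and 1 lower adjusted over the list alone), with a median of -0.13 (adjusted p = 0.484). Apoptosis regulators (0 of 20 called, median -0.0046), immediate early and MAPK output genes (0 of 24, -0.025), NRF2 and aldo-keto reductase genes (0 of 18, 0.019), cholesterol synthesis (0 of 20, 0.017) and cytosolic heat shock proteins (0 of 15, 0.058) did not pass. None of the 18 genes was called in the same direction against untransfected cells, and GPNMB was higher there by 0.92 (adjusted p = 0.000356). MAN1A1 (-0.156), DHRS2 (-0.135), COLCA1 (-0.105) and ROBO1 (-0.0651) also turned direction there, without being called. The count lay between 0 and 8 when any 1 of 20 of the 24 arrays was left out, and was 0 without either vector array.

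Over both lines 14 genes were called, 4 higher and 10 lower. SNAI2, MAN1A1, EPHA7 and IGFBP3, an insulin-like growth factor binding protein, rose by 0.47 ± 0.079, 0.46, 0.43 and 0.29. RIPOR2 fell by 0.57 ± 0.048 (adjusted p = 2.5e-05), TMEM45B by 0.49, TNFSF10 by 0.39, KLK3 by 0.38, SYT4 by 0.36 and DSC3 by 0.35. GRPR and PLAAT3 fell by 0.31 and 0.23. Several of these averages came mostly from 1 line. In 22RV1 the differences were -0.082 for RIPOR2, -0.054 for KLK3, -0.071 for DSC3 and 0.044 for SYT4, against -1.06, -0.71, -0.62 and -0.76 in LNCaP, and TNFSF10 differed by -0.68 in 22RV1 and -0.093 in LNCaP. Against untransfected cells SNAI2 (0.324), MAN1A1 (-0.156) and TNFSF10 (-0.151) were not called in 22RV1. In LNCaP RIPOR2 was called against them (-0.462). TMEM45B (-0.288), KLK3 (-0.294), SYT4 (0.215), DSC3 (-0.0727), GRPR (-0.178) and PLAAT3 (-0.252) were not. MYCL differed from vector by 0.19 ± 0.054 over both lines (adjusted p = 0.523). Of the lists over both lines, cytosolic ribosomal proteins (median 0.076, 49 of 51 above 0), oxidative phosphorylation (0.095, 31 of 33) and DNA replication (0.077, 33 of 34) had 0 members called and adjusted p = 0.577 with an estimated correlation, as none of the 11 lists that passed with the preset correlation passed with it. The effect of the constructs differed between the lines in 10 genes. GPNMB (0.93 ± 0.13) and TTR (0.72 ± 0.099), which encodes a thyroid hormone carrier, had a more positive effect in LNCaP. SLITRK3 (-1.17), RIPOR2 (-0.98), CADPS2 (-0.84), SYT4 (-0.80), COLCA1 (-0.67), KLK3 (-0.66) and DSC3 (-0.55) had a more negative one, as did OR51E1 (-1.25). With untransfected cells as control the line difference turned direction for GPNMB (-0.37), SLITRK3 (0.14) and SYT4 (0.67). Without 22RV1 vector replicate 1 or LNCaP vector replicate 1 the 14 genes became 4, and without any 1 of the 4 vector arrays the 10 genes became 2. Omitting LNCaP NM_005376 replicate 2 or BC011864 replicate 2 gave 22 and 16 for the latter.

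The BC011864 pool of LNCaP had 205 genes higher and 172 lower than vector. The interferon-inducible chemokine CXCL10 rose by 1.89 ± 0.13 (SE, adjusted p = 9.52e-07) and the interferon-inducible GTPase GBP1 by 1.63 ± 0.16. TRGC2, ARHGAP28 and the glutathione transferase GSTA1 rose by 1.63, 1.32 and 1.27. The replication-dependent histone gene H3C11 fell by 2.70 ± 0.13 (adjusted p = 1.06e-08). UGT2B11, a glucuronosyltransferase, fell by 1.94, S100A7 by 1.69, the prostate noncoding RNA PCAT1 by 1.56 and the lysyl hydroxylase PLOD2 by 1.51. Both BC011864 arrays lay beyond both vector arrays for each of these genes.

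Of the p53 target genes 9 of 22 were called higher in this pool and 0 lower (13 higher adjusted over the list alone), and 4 of the 13 not called lay below 0. Their median was 0.30 (camera adjusted p = 7.83e-18, and 0.000117 with an estimated correlation). ZMAT3, an RNA-binding protein, rose by 0.78 ± 0.078, TIGAR, a phosphatase acting on fructose bisphosphate, by 0.88 ± 0.15, the stress protein SESN1 by 0.70 and TP53INP1 by 0.66. Against untransfected cells the list median was 0.33. Genes repressed by the androgen receptor fell, with 3 of 9 called (5 adjusted over the list alone) and a median of -0.39 (adjusted p = 5.36e-05, and 0.01 with an estimated correlation). The 3 were UGT2B11, UGT2B28 (-1.25) and UGT2B17 (-0.79), paralogous glucuronosyltransferases whose probes may share sequence. Against untransfected cells that list no longer passed (median -0.31, adjusted p = 0.0794, the highest over its alternatives).

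Other lists in the BC011864 LNCaP pool held only with the preset correlation or not at all. Androgen-induced genes had 5 of 26 called higher, among them MAF (0.57), TRPM8 (0.50) and the acid phosphatase ACP3 (0.60), and 1 lower, KLK3 (-0.88), or 7 and 2 adjusted over the list alone, with a median of 0.15 (adjusted p = 0.338 with an estimated correlation). Interferon-stimulated genes had 3 of 37 called higher, OASL (0.45), RIGI (0.59) and RSAD2 (0.38), 12 adjusted over the list alone, and a median of 0.066 (0.185 estimated). MYC-repressed genes had 3 of 14 called higher, GADD45A (0.53), KLF6 (0.33) and CDKN1A (0.28), with a median of -0.051 and a mean of -0.004, while camera placed the list above other genes (adjusted p = 0.337). Ribosome biogenesis genes had a median of 0.21 with 39 of 40 above 0 and 0 called (6 adjusted over the list alone; adjusted p = 8.73e-16, and 0.185 estimated). The hypoxia-inducible VEGFA fell by 1.00 as the 1 of 28 glycolysis and hypoxia genes called (median -0.15, 0.647 estimated). NQO1 and SLC7A11 fell by 0.87 and 0.71 as 2 of 18 NRF2 and aldo-keto reductase genes called, a list with 9 members above 0, 9 below and a median of 0.012 (0.864 estimated). Smooth muscle actin ACTA2 and vimentin rose by 0.87 and 0.46 as 2 of 22 mesenchymal markers called, and SERPINB5 rose by 0.65 as 1 of 13 basal epithelium markers. The count of 377 genes was 61 with LNCaP fitted alone, 1091 with array spread as a covariate and 3165 against untransfected cells, where 327 of the 377 were called in the same direction. It was 160 without BC011864 replicate 2, 613 without replicate 1, 112 and 157 without vector replicates 1 and 2, and 583 without either NM_005376 array.

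**Figure D3:**
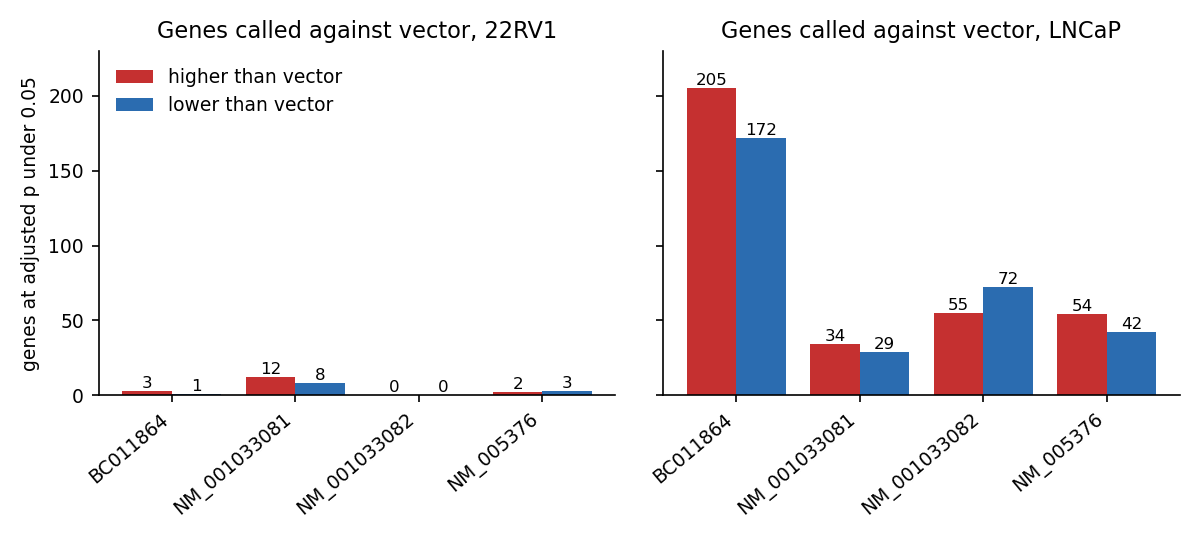
Number of genes at adjusted p under 0.05 against vector for each construct, with 22RV1 on the left and LNCaP on the right; red bars count genes higher than vector and blue bars genes lower. BC011864 in LNCaP has 205 higher and 172 lower, and no 22RV1 pool exceeds 12 higher.

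**Figure D4:**
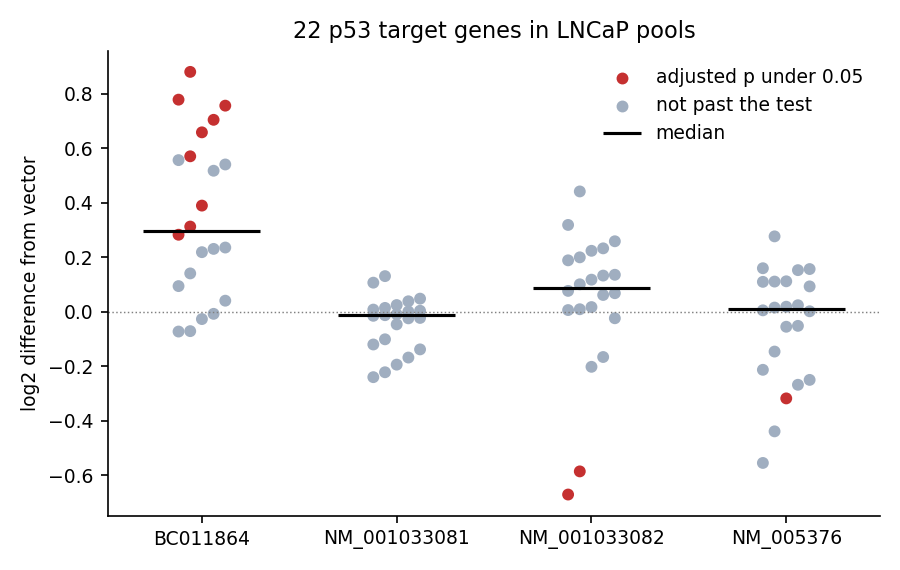
Log2 differences from vector of 22 p53 target genes in the 4 LNCaP construct pools; each point is a gene, red where adjusted p was under 0.05, and black lines are medians. The median is 0.30 for BC011864 and lies between -0.014 and 0.089 for the other pools.

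The NM_001033082 pool of LNCaP differed from vector in 127 genes, 55 higher and 72 lower. KLK3 fell by 1.59 ± 0.098 (SE, adjusted p = 4.05e-07), from 11.5 ± 0.1 to 9.88 ± 0.043 (SD, n = 2). The peptide hormone gene RLN1 fell by 2.27, the metallothionein MT1G by 2.13, the BMP receptor BMPR1B by 1.44 and SLITRK3 by 1.42. EPHA7, an ephrin receptor, rose by 1.77 ± 0.13 (adjusted p = 3.25e-06), the glucagon gene GCG by 1.21, TTR by 1.19, BRINP3-DT by 1.00 and the transfer RNA gene TRA-TGC5-1 by 0.99. Amino acid and ATF4 response genes fell, with 3 of 26 called (16 adjusted over the list alone) and a median of -0.32 (camera adjusted p = 3.78e-26, and 0.0339 with an estimated correlation). The 3 were the alanyl-tRNA synthetase AARS1 (-0.83 ± 0.15), DDIT4 (-0.64) and cystathionine beta-synthase CBS (-0.51). Androgen-induced genes had 4 of 26 called lower, KLK3, TMPRSS2 (-0.87), ACP3 (-0.67) and CENPN (-0.62), or 1 higher and 8 lower adjusted over the list alone, with a median of -0.18 (adjusted p = 3.12e-13, and 0.0757 estimated). Of the 127 genes 57 were called in the same direction against untransfected cells. The count was 16 with LNCaP fitted alone. It was 50 and 38 without NM_001033082 replicates 1 and 2, 26 and 48 without vector replicates 1 and 2, and 220 without either NM_005376 array.

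The NM_005376 pool of LNCaP had 54 genes higher and 42 lower than vector. The proteasome assembly factor PSMD5 fell by 1.59 ± 0.16 (adjusted p = 0.000128), GPR158 by 1.36, RIPOR2 by 1.30, the ephrin receptor EPHA3 by 1.27 and the imprinted gene PEG3 by 1.17. The small Cajal body RNAs SCARNA1 and SCARNA10 rose by 1.64 and 1.36, the prostate noncoding RNA PCGEM1 by 1.11, ZNF124 by 1.14 and TRA-TGC5-1 by 1.11. Small nucleolar RNAs had 16 of 323 called higher and 0 lower (66 higher adjusted over the list alone), with a median of 0.26 (camera adjusted p = 3.47e-14, and 0.36 with an estimated correlation). SNORA26 rose by 1.85 and SNORA51 by 1.28. Against untransfected cells the list median was 0.047 with 0 members called. KLK2 (-0.87) and NDRG1 (-0.94) were the 2 of 26 androgen-induced genes called (9 lower adjusted over the list alone), with a list median of -0.22 (adjusted p = 0.175 with an estimated correlation). Of the 96 genes 11 were called in the same direction against untransfected cells. Array weights reduced the count of 96 to 5 and array spread as a covariate raised it to 1615. It was 911 without NM_005376 replicate 1, 14 without either vector array, 284 without either 22RV1 untransfected array, and 47 to 62 without any 1 of 8 others.

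In the NM_001033081 pool of LNCaP, 34 genes were higher and 29 lower than vector. PLXDC2 rose by 1.33 ± 0.11 (adjusted p = 1.74e-05), the pattern recognition receptor CLEC7A by 1.14, S100A7 by 1.07, the phospholipase PLA2G2A by 0.99 and TNFSF10 by 0.98. SYT4 fell by 1.57 ± 0.1 (adjusted p = 6.97e-07), the phosphodiesterase PDE10A by 1.33, TNFRSF19 by 1.25 and the bicarbonate transporter SLC4A4 by 1.04, and RLN1 also fell (-1.495). Vimentin rose by 0.67 as 1 of 22 mesenchymal markers called. TRPM8 and SLC45A3 fell by 0.73 and 0.40 as 2 of 26 androgen-induced genes. DNA replication genes had a median of 0.19 and 0 of 34 called (adjusted p = 2.53e-13, and 0.144 with an estimated correlation). Of the 63 genes 38 were called in the same direction against untransfected cells. The count of 63 was 11 with LNCaP fitted alone, 24 and 34 without NM_001033081 replicates 1 and 2, 20 and 30 without vector replicates 1 and 2, and 100 without either NM_005376 array.

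Single constructs called few genes in 22RV1. In the BC011864 pool ANXA1, a phospholipid-binding protein, rose by 1.45 ± 0.13 (adjusted p = 0.000124), DHRS2 and RGS5 rose by 0.76 and 0.63, and GPNMB fell by 0.98. The NM_001033081 pool had 12 genes higher and 8 lower. EPHA7, MMP16, TDRD9, the retinaldehyde dehydrogenase ALDH1A1 and ROBO1 rose by 0.76 to 0.89, and UGT1A3, the sodium channel subunits SCNN1G and SCNN1B, TNFSF10 and GPNMB fell by 1.10, 0.96, 0.91, 0.85 and 0.72. In the NM_005376 pool the protease inhibitor A2M rose by 1.09 ± 0.094 (adjusted p = 6.81e-05), TMEM132D-AS1 rose by 0.98 and TNFSF10 fell by 0.69. The NM_001033082 pool had 0 genes past the limma threshold and 3117 at an unadjusted p under 0.05. Array weights gave 6876 calls there and quantile normalization 33. Called in the same direction against untransfected cells were 1 of the 4 BC011864 genes, 0 of the 20 NM_001033081 genes and 3 of the 5 NM_005376 genes. GPNMB turned direction there in the BC011864 and NM_001033081 pools, and in vector it stood 1.46 above untransfected cells. The count of 20 for NM_001033081 against vector was 0 without NM_001033081 replicate 2 or vector replicate 1, 11 without NM_001033081 replicate 1, 2 without vector replicate 2 and 45 without either LNCaP NM_005376 array.

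The 4 constructs differed from each other in 1541 genes in LNCaP and 32 in 22RV1 by the moderated F test. Compared pair by pair in LNCaP, BC011864 differed from NM_001033081, NM_001033082 and NM_005376 in 859, 993 and 1929 genes. The other LNCaP pairs gave 340, 280 and 64. In 22RV1, NM_005376 differed from BC011864, NM_001033081 and NM_001033082 in 18, 38 and 31 genes, and every other pair gave 1. In LNCaP 547 genes were called against vector in at least 1 construct. The 4 genes lower in all 4 pools, named after their values were seen, were DSC3, OR51E1, RIPOR2 and RNU6-81P, and 0 were higher in all. These comparisons share the vector arrays. In vector against untransfected cells the 4 genes had risen by 0.548, 1.16, 0.599 and 0.815 in the same order. Of them the mean of the constructs called only RIPOR2 against untransfected cells. Against vector, constructs called 34 genes in opposite directions. BC011864 and NM_001033081 shared 1 higher and 6 lower calls and opposed each other in 23, against 0.283 and 0.203 shared calls for independent lists. PLXDC2, S100A7, TNFSF10, TNFRSF19 and PDE10A were among the 23, the first 3 lower with BC011864 and higher with NM_001033081 and the last 2 the reverse. NM_001033082 and NM_005376 shared 10 higher and 21 lower calls, with 0 opposed, against 0.121 and 0.123 for independent lists. Simulations shared 0 calls, but they held no effects to call. They cannot show how many shared calls the vector arrays add. The log2 differences of these 2 pools correlated across genes at r = 0.672, with a covariance of 0.0237. The simulations, with an equal spread in all groups, gave 0.5 and 0.00929. The SD of replicate differences was 0.161 for NM_001033082, 0.357 for NM_005376 and 0.135 for vector. The simulated values therefore do not measure what these vector arrays add. With the differences of 1 pool taken from vector and of the other from untransfected cells, which share no control, r averaged -0.0205 over both ways round. In that average the correlation was not seen with untransfected cells as the second control. With 1 vector array taken for each pool, chosen after seeing the data, no array was shared and r was 0.457 and 0.514 the 2 ways round. The labels place both vector arrays in 1 pool, so a shift of that pool stays in both differences and part of the correlation may come from it. In 22RV1 the NM_001033081 and NM_001033082 pools, with 20 and 0 genes called, correlated at r = 0.80 with a covariance of 0.0265. The simulated covariance, with an equal spread, was 0.00927. There r averaged 0.575 over both ways round with untransfected cells as the second control, and was 0.615 and 0.541 with 1 vector array for each pool. The interquartile range was 2.93 to 3.08 on the arrays of these pools. It was 2.84 and 2.89 on the vector arrays and 2.89 and 2.92 on the untransfected arrays of the line. Whether array spread carries part of this correlation was not tested. BC011864 correlated with the other constructs in LNCaP at 0.117 to 0.204, with covariances of 0.00407 to 0.00592. These lay below the simulated values, which assume an equal spread and so do not measure what the tighter vector arrays add. With 1 vector array for each pool, the covariances were 0.000681 with NM_001033081, -0.000482 with NM_001033082 and 0.00137 with NM_005376. Genes are not independent replicates. The F test count in LNCaP was 253 with the line fitted alone, 790 without BC011864 replicate 2, 930 without NM_001033081 replicate 1, and 3013 and 4833 without NM_005376 replicates 1 and 2. In 22RV1 it was 2 and 6 without NM_005376 replicates 1 and 2, 12 to 20 without any 1 array of the NM_001033081 and NM_001033082 pools, and 56 without either LNCaP NM_005376 array.

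Vector pools also differed from untransfected cells. In 22RV1, GPNMB rose by 1.46 ± 0.11 (adjusted p = 1.33e-05), and SPOCK1, the heat shock protein HSPA1A, ABCC11, NPNT, ARHGEF38, FGF13 and TTC39A rose by 0.42 to 0.60. ALB, which encodes albumin, fell by 1.04, MAN1A1 by 0.80, the hyaluronan synthase HAS2 by 0.68 and A1CF by 0.63. CBLN2, TRIB1, the growth factor HGF, the amino acid transporter SLC7A5, DHRS2 and ROBO1 fell by 0.56 to 0.62. The count was 22, with 8 higher and 14 lower. In LNCaP, PEG3, SYT4, the helicase DDX60, RIPOR2 and DSC3 rose by 0.99, 0.97, 0.88, 0.60 and 0.55, and 7 genes were called in all. OR51E1 rose there by 1.16 ± 0.12 (adjusted p = 0.000491), and SNORA51 was the 1 gene that fell. With the preset correlation 14 lists passed in LNCaP vector cells, 13 above other genes and 1 below, and 7 passed in 22RV1, 1 above and 6 below. In LNCaP mitosis genes had a median of 0.23 (camera adjusted p = 1.24e-09, and 0.376 with an estimated correlation) and small nucleolar RNAs, the list below, -0.27 (1.06e-08, and 0.376 estimated). In neither line did any list pass with an estimated correlation. In 22RV1 the count was 2 and 3 without vector replicates 1 and 2, 14 and 3 without untransfected replicates 1 and 2, and 37 without either LNCaP NM_005376 array. In LNCaP it was 0 with the line fitted alone, 2 without either vector array, 3 and 93 without untransfected replicates 1 and 2, and 15 to 22 without any 1 array of the 22RV1 untransfected, LNCaP BC011864 and LNCaP NM_005376 groups.

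The untransfected lines differed throughout the transcriptome. UGT2B17 was higher in LNCaP by 6.15 ± 0.17 log2 units as deposited and 6.7 after quantile normalization. The metalloprotease MME (neprilysin), UGT2B11, the zinc transporter SLC30A4, the kinase subunit PRKACB, DNASE2B, IRX4-AS1, NBEAP1, RAB25 and UGT2B15 were higher by 3.71 to 4.57 (4.385 to 5.19 after quantile normalization). KLK3 was higher by 3.32 (3.84 after quantile normalization). The G protein regulator RGS2 was lower by 7.54 log2 units in LNCaP than in 22RV1 (log2 difference -7.54, and -7.11 after quantile normalization). SSX3 (-6.90), TSPAN8 (-5.97), ALB (-5.88), S100A10 (-5.81), PEG10 (-5.76), PTPRB (-5.57), SPESP1 (-5.49), SCG3 (-5.37) and GUCY1A2 (-5.31) followed, at -6.485 to -4.80 after quantile normalization. Both LNCaP arrays lay beyond both 22RV1 arrays for each gene named here. UGT2B17 averaged 3.93 in 22RV1 and RGS2 3.96 in LNCaP, below the lower quartile of those arrays. Detection was not tested, so such differences may be lower bounds.

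Counts between the lines followed the scaling. The median gene differed by -0.51 as deposited, with 1205 genes called higher and 18432 lower in LNCaP, a share of 6.14% higher. After quantile normalization the median was 0.054, with 6646 higher and 5644 lower, a share of 54.1%. MYCL differed by -0.45 ± 0.097 as deposited and by 0.18 ± 0.11 after quantile normalization, where it was not called. DNA replication genes were lower in LNCaP under both scalings, with 33 of 34 and 31 of 34 called lower (POLE, -2.04 and -1.495), and camera adjusted p = 0.129 and 0.00531 with an estimated correlation. The p53 target genes stood above other genes in LNCaP in both (adjusted p = 0.0088 and 0.00531 with an estimated correlation), although their deposited median was -0.048 with 8 higher and 9 lower and their quantile median 0.56 with 15 higher and 2 lower. GDF15 (3.21 and 3.73) and SESN1 (2.02 and 2.70) were higher under both. Amino acid and ATF4 response genes had medians of 0.22 and 0.80, with 12 and 23 of 26 higher and 4 and 2 lower (adjusted p = 0.0969 and 0.00758 with an estimated correlation). Androgen-repressed genes had medians of 0.76 and 1.37, with 6 and 7 of 9 higher (adjusted p = 0.00113 and 0.268 with an estimated correlation). Neuroendocrine and neuronal markers had 23 of 27 lower as deposited and 15 lower with 5 higher after quantile normalization, with SCG3 and SNAP25 (-2.90 and -2.37) lower in both.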

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

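The tests against untransfected cells, of single arrays, of MYCL level and of array spread in the model were chosen after the result was seen. The test for admixed 22RV1 cells, the regroupings of arrays and a correlation of small nucleolar RNAs with array spread were set before their results were seen.

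The effect of the mean construct against vector differed between the lines, by a test of the difference itself, for 10 genes. As LNCaP minus 22RV1 on the log2 scale, it was -0.837 for CADPS2, -0.674 for COLCA1, -0.55 for DSC3, 0.933 for GPNMB, -0.66 for KLK3, -1.25 for OR51E1, -0.979 for RIPOR2, -1.17 for SLITRK3, -0.801 for SYT4 and 0.722 for TTR. With untransfected cells as control it turned direction for GPNMB (-0.37), SLITRK3 (0.144) and SYT4 (0.667). In 11 of 100 regroupings of the transfected arrays within each line, the real one included, at least 10 genes were called. The highest other regrouping called 8742, and which arrays it put together was not examined. For the 14 genes of the mean construct over both lines, 6 of 100 regroupings called as many, with 806 the highest other. Both counts met the bound set beforehand for chance, so chance was not excluded for either. The regroupings carry the differences between construct pools and break the pools of 2 arrays, which limits what they can decide. With the pools kept whole, 22 of the 25 choices of which pool in each line stood for vector called at least 14 genes, and the highest other called 751. This too met the bound set beforehand for chance, which would have been argued against only if no other choice reached the count. For the line difference 23 of the 25 called at least 10, and the highest other called 574. Set against the other transfected pools of LNCaP, vector differed in 28 genes and the single construct pools in 176 to 1697. The 28 are the genes of the mean construct against vector, with the direction turned, and not a further result.

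For the genes called with the mean construct, a candidate explanation is that the vector pool itself stands apart from the line. The difference from untransfected cells was a median of 0.4 of the difference from vector over the 28 LNCaP genes (quartiles 0.112 and 0.595) and 0.363 over the 18 genes of 22RV1 (quartiles -0.0756 and 0.555). In LNCaP 27 of 28 genes, and in 22RV1 all 18, had moved the opposite way in vector against untransfected cells. The genes were picked for their difference from vector, which by itself lowers these shares, so a drift of the vector pools and an effect of MYCL cannot be told apart for either line. QNG1 and RIPOR2, with TTR and CLEC7A in the other direction, are among the 7 LNCaP genes called against both controls.

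The rise of p53 target genes in the LNCaP BC011864 pool was weighed against 4 explanations. Admixed 22RV1 cells would have raised the 100 genes furthest above LNCaP in 22RV1, and these had a median of -0.0959 (quartiles -0.144 and -0.0532). Between the untransfected lines, the p53 target genes stood above other genes in LNCaP under both scalings. After quantile normalization their median was 0.558, with 15 of 22 higher in LNCaP and 2 lower. Admixture would thus not be expected to raise this list, and testing it adds little. A vector pool standing apart is argued against by the list median of 0.33 against untransfected cells, and a single outlying array by a median of 0.281 or more with either array omitted. The MYCL level that the probe set reads is argued against because the NM_001033082 and NM_005376 pools, where MYCL was highest, had list medians of at most 0.0889, and BC011864 exceeded each of them (camera adjusted p = 0.00126 and 0.000172 with an estimated correlation). Open are a change that arose in this pool by selection or culture, which 1 pool per construct cannot separate from the construct, and a BC011864 product that the probe set does not read; both may apply and neither was tested.

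The small nucleolar RNAs that were higher in the LNCaP NM_005376 pool were tested against array spread first by correlation, where an r beyond 0.7 was to count for it and under 0.3 in size against it. Across the 12 LNCaP arrays Pearson's r of their mean with the interquartile range was -0.318 (permutation p = 0.318, adjusted 0.318) and Spearman's rho -0.245 (permutation p = 0.444, adjusted 0.444), with r = 0.13 without the 2 farthest arrays, which decided nothing by those bounds; in 22RV1 r was 0.624 (permutation p = 0.0298, adjusted 0.0596) and rho 0.685 (permutation p = 0.0166, adjusted 0.0332), resting on 2 arrays without which r was 0.426. It was then replaced, with this outcome known, by a model holding the interquartile range. There the list median was 0.259 (quartiles 0.0782 and 0.545, against 0.26 without the range) and 48 of 323 were called. The range was 2.881 and 3.151 on the NM_005376 arrays and 3.038 and 3.048 on the vector arrays. The group means of the range hardly differ, so the model could barely move this median whatever the cause. Spread as the cause was therefore not decided. Against untransfected cells the median of the small nucleolar RNAs was 0.047 (quartiles -0.0863 and 0.164) and 0 were called. A low level in the vector pool is therefore a candidate explanation that cannot be told apart from an effect of the construct. Recovery of small RNA during extraction was not tested.

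Rows without a gene name, which no comparison above used, also carried differences: 22 of 1564 were called for BC011864 against vector in LNCaP.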

How the results depend on the processing

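Array spread as a covariate, array weights and leaving out a pair of LNCaP arrays were chosen after seeing the data; the other alternatives were set before the data were examined. Of 148 called gene results, 55 kept call and direction under every alternative other than the other control, and 1 was reversed. Of the 104 called gene results with a counterpart against untransfected cells, 38 were the same there, 56 lost their call and 10 were reversed. The 5 lists that passed with an estimated correlation were run under the other alternatives with the preset correlation, and kept direction and call there except androgen-repressed genes for BC011864 in LNCaP against untransfected cells (adjusted p = 0.0794). With quantile normalization and an estimated correlation together, androgen-repressed genes between the lines did not pass (adjusted p = 0.268). Signal over background was not available in the values used, so its limit on low genes was not measured. Averaging the rows of a gene was not run, since each gene had 1 row. For every changed count below the cause was not tested, with these exceptions. Fitting a line alone leaves 6 of 12 residual degrees of freedom, and leaving low values out tests fewer genes. Leaving out an array of a group outside a comparison keeps its log2 differences, so the count moves only through the shared estimate of spread. That estimate takes all groups as equal, while the SD of replicate differences ran from 0.131 to 0.357. P-values may then be too small for the widest groups and too large for the tightest.

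In the counts below, "mean" is the mean of the 4 constructs against vector, and single constructs are against vector. With each cell line fitted alone, counts in 22RV1 were 9 for the mean, 39 for NM_001033081, 11 for NM_001033082 and 35 for vector against untransfected. In LNCaP they were 5 for the mean, 61 for BC011864, 11 for NM_001033081, 16 for NM_001033082, 11 for NM_005376, 0 for vector against untransfected and 253 among constructs. With low values left out, counts were 8 for the mean in 22RV1, 8 for the mean over both lines, 11 for NM_001033081 and 3 for NM_005376 in 22RV1, 3 for vector against untransfected in LNCaP and 20 among constructs in 22RV1. With trend and robust variance the mean in 22RV1 gave 4, and with unnamed rows included NM_001033082 in 22RV1 gave 1.

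With quantile normalization, counts were 23 for the mean over both lines, 17 for the line difference, 9 for BC011864, 86 for NM_001033081 and 33 for NM_001033082 in 22RV1, 237 for NM_001033082 and 146 for NM_005376 in LNCaP, 48 for vector against untransfected and 63 among constructs in 22RV1, and 12290 between the lines. MYCL between the lines was reversed there, at 0.185.

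With untransfected cells as control, counts in 22RV1 were 0 for NM_001033081, 69 for NM_001033082 and 31 for NM_005376, and in LNCaP 3165 for BC011864, 124 for NM_001033081 and 22 for NM_005376. Among genes named by rule, reversed for the mean in 22RV1 were MAN1A1 (-0.156), DHRS2 (-0.135), COLCA1 (-0.105) and GPNMB (0.92), and in LNCaP SYT4 (0.215); among all genes called, the sign turned for 5 of 18 and 4 of 28, the others being ROBO1 (-0.0651) in 22RV1 and PEG3 (0.285), RNU4-2 (-0.225) and SNORA26 (-0.199) in LNCaP. Reversed for the line difference were GPNMB (-0.37), SLITRK3 (0.144) and SYT4 (0.667). GPNMB was reversed in 22RV1 for BC011864 (0.474) and NM_001033081 (0.735).

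With the replicate number as a replicate block within each line, counts were 7 for BC011864, 32 for NM_001033081, 14 for NM_001033082, 36 for vector against untransfected and 53 among constructs in 22RV1, and 224 for NM_005376, 11 for vector against untransfected and 2377 among constructs in LNCaP. Replicate differences correlated above 0.1 for 7 of 15 pairs of groups in 22RV1 and 6 of 15 in LNCaP, so the numbers were not taken to pair arrays. Across genes r ran from -0.357 to 0.507 in 22RV1 and from -0.154 to 0.745 in LNCaP. Some groups therefore shared array-wide differences, while the fit treats arrays as independent.

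With array spread as a covariate, counts were 5 for the mean in 22RV1, 173 in LNCaP, 32 over both lines and 27 for the line difference. They were 27 for BC011864, 112 for vector against untransfected and 155 among constructs in 22RV1, and 1091 for BC011864, 313 for NM_001033081, 633 for NM_001033082, 1615 for NM_005376, 13 for vector against untransfected and 3371 among constructs in LNCaP. With array weights, which were 0.191 at the lowest (LNCaP NM_005376) and 2.2 at the highest, counts were 144 for the mean in 22RV1, 88 in LNCaP, 75 over both lines and 75 for the line difference. In 22RV1 they were 52 for BC011864, 77 for NM_001033081, 6876 for NM_001033082, 22 for NM_005376, 66 for vector against untransfected and 455 among constructs, and in LNCaP 181, 735, 2483, 5 and 453 for the constructs in the same order and among constructs. With the second LNCaP BC011864 and NM_005376 arrays left out, counts were 29 for the mean in 22RV1, 62 in LNCaP, 25 over both lines and 40 for the line difference. In 22RV1 they were 7 for BC011864, 59 for NM_001033081, 81 for NM_001033082, 51 for vector against untransfected and 72 among constructs, and in LNCaP 129 for NM_001033081, 335 for NM_001033082, 1587 for NM_005376 and 30 for vector against untransfected.

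Leaving out each array in turn leaves 1 group with a lone array, assumed to vary like the other groups. Counts then ranged from 0 to 22 for the mean in 22RV1, 4 to 45 in LNCaP, 4 to 20 over both lines and 2 to 22 for the line difference. In 22RV1 they ranged from 1 to 7 for BC011864, 0 to 45 for NM_001033081, 0 to 16 for NM_001033082, 1 to 7 for NM_005376, 2 to 37 for vector against untransfected and 2 to 56 among constructs. In LNCaP they ranged from 112 to 613 for BC011864, 20 to 100 for NM_001033081, 26 to 220 for NM_001033082, 14 to 911 for NM_005376, 2 to 93 for vector against untransfected and 790 to 4833 among constructs, and between the lines from 16095 to 20401. Of these counts 128 moved by over 1.5 times and 280 did not. Those not given beside their result were, in 22RV1, BC011864 (1 without vector replicate 1, 2 without BC011864 replicate 2, 7 without either LNCaP NM_005376 array), NM_001033082 (1 without either BC011864 array, 15 or 16 without any 1 LNCaP BC011864 or NM_005376 array) and NM_005376 (1 without NM_005376 replicate 2 or any 1 vector or NM_001033082 array, 2 without NM_005376 replicate 1). Over both lines, counts were 5 to 9 without any 1 of 16 further arrays, namely 22RV1 vector replicate 2, LNCaP vector replicate 2, the other 22RV1 arrays and those of NM_001033081 and NM_001033082 in LNCaP.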

Other observations

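Of the 23 genes called in opposite directions in the LNCaP BC011864 and NM_001033081 pools, those named here were chosen after their values were seen. The ion channel TRPM8 was 0.50 higher with BC011864 and 0.73 lower with NM_001033081 (log2 differences 0.50 and -0.73), and the prostate transporter SLC45A3 followed (0.34 and -0.40). The BMP pseudoreceptor BAMBI (0.86 and -0.47), the fatty acid elongase ELOVL7 (0.95 and -0.95), the glycosyltransferase GCNT1 (0.80 and -0.89), the glycine decarboxylase GLDC (0.47 and -0.59) and thrombospondin THBS1 (0.48 and -0.45) had the same pattern. The thymosin TMSB4X (-0.79 and 0.96), the zinc transporter SLC39A8 (-0.67 and 0.78), ALDH3B2 (-0.37 and 0.68) and FCAMR (-0.75 and 0.93) were lower with BC011864 and higher with NM_001033081. Each pool was called against the same vector arrays, which by chance pull both differences the same way. Against untransfected cells 14 of the 23 were called in both pools and 9 were not, among them SLC45A3, BAMBI, ELOVL7, THBS1, TMSB4X and ALDH3B2. PDE10A (1.24 and -1.28), PLXDC2 (-1.39 and 1.25) and S100A7 (-1.42 and 1.34) were among the 14.

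Histone genes under current symbols, 63 measured and added after seeing the data, had 1 member called in the LNCaP BC011864 pool, H3C11, and a median of -0.064. H3C11 read 5.46 and 6.05 on the 2 BC011864 arrays, against 8.35 to 8.54 on the other 10 LNCaP arrays. In 22RV1 it read 10.7 to 11.1 as deposited, which is not compared with LNCaP because the array medians of the lines differ. Each pool set against the other 4 transfected pools of its line gave 1697 genes for BC011864 in LNCaP, 391 for NM_001033081, 364 for NM_005376, 176 for NM_001033082 and 28 for vector. In 22RV1 the counts were 4 for BC011864, 20 for NM_001033081, 21 for NM_005376, 0 for NM_001033082 and 18 for vector. The vector counts repeat the mean of the 4 constructs against vector with the direction turned.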
